A study of Homo sapiens with 12 samples.

How the data were processed

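Messenger RNA was measured in BxPC-3 cells, an established human pancreatic ductal adenocarcinoma line, on 12 two-colour Agilent whole-genome arrays. Per the labels, 4 cultures per condition went overnight without glucose and glutamine. They then spent 6 h in medium with 25 mM glucose, with 2 mM glutamine or with both. Total RNA was amplified from its polyadenylated fraction into dye-labelled cRNA. The 12 arrays form 3 groups of 4 replicates, named here by the added nutrient: glucose, glutamine, and glucose plus glutamine. On every array the depleted cells were in the green channel (Cy3) and the nutrient-treated cells in the red channel (Cy5). No array had the dyes exchanged, so a dye effect particular to a gene stays in each ratio to depleted cells and cancels between nutrient groups. The labels do not say whether each array had its own depleted culture or RNA from a shared pool. If it was a pool, the spread between arrays leaves out the spread of depleted cultures.

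The authors deposited a scanner table for each array, written by Agilent Feature Extraction 9.5.1.1, and a series-wide set of ratios. Per the file headers, the mean spot signal and the median local background are given as intensity before background subtraction and dye normalization. Per the file headers, the software's own log ratio is in log10 units, red over green, after spatial detrending, background subtraction, multiplicative detrending and linear and LOWESS dye normalization. The deposited series table holds log2 ratios, and these were equal to the log10 ratios times the base-2 logarithm of 10 within 1.7e-06 at all 419279 values given, with 101233 entries empty. The medians of its 12 columns lay between -0.0207 and 0.0117. Spot signal and background were the starting point, and the software's ratio and the series table served as alternatives.

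Each array held 45015 spots, of which 43376 were not controls and covered 41000 probes. The median signal per array was 229 to 337 in green and 364 to 473 in red, over a median background of 35 to 68 and 51 to 59.5. Well above background were 64.4% to 72% of probes in green and 67.3% to 80.1% in red. Outlying spots numbered 101 to 260 per array and saturated probes 0 to 2. The number of arrays limits the precision of every value. Intensities were background-corrected with limma 3.58.1 in R 4.3.3 (normexp, offset 50) and normalized within each array by loess, with control and outlying spots at weight 0. Outlying spots were then set aside and the spots of a probe averaged. Probes well above background in either channel on at least 4 of the 12 arrays were kept, which left 30694. Each gene was represented by its brightest probe on average, which gave 22848 genes.

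Gene symbols came from the array files, brought up to date through the transcript accessions of a reference table for GRCh38.p14 that was used for names alone. Of the probes, 23434 matched it directly and 1745 through a shared file name, while 15821 kept the name the file gives. Probe positions are those of the array design on the build hg17. No annotation of that build was at hand, so the exon or untranslated region under a probe is not stated. Many genes have transcripts so alike that a probe may read more than 1 of them (HSPA1A and HSPA1B, HSPA6, the CXCL1 to CXCL3 group, ANP32D, GLUD2, AKR1C1).

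A linear model with 1 mean per group was fitted to the log2 ratios of all 12 arrays with limma (lmFit and eBayes). It had 9 residual degrees of freedom, 5.1 prior degrees of freedom and a median residual SD of 0.0769. Each group was tested against 0, which is the depleted level, and the 3 pairs of groups against each other. The interaction was the ratio with glucose plus glutamine minus the ratios with each nutrient alone. It holds any gene-specific dye effect with its sign turned. Tests were two-sided, with the Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Standard errors (SE) come from the limma fit.

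The following was fixed before the data were examined: the tests, the alternatives, 25 gene lists and the rule for naming genes. The rule took the 10 highest and 10 lowest changes in the 3 comparisons with depleted cells and in glucose plus glutamine against glucose, and the 5 highest and 5 lowest in the other pair of comparisons. Such a gene had to pass the threshold, to have 1 sign on all 4 arrays (between groups, no overlap of arrays), a symbol, and a mean brightness at or over the median of 10.1. From each list past its threshold it allowed up to 4 members of lowest p in the list's direction and up to 2 that moved the other way, of which 2 and 1 were taken. TXNIP, ARRDC4, ASNS, DDIT3, HSPA5, SLC2A1, HK2 and MYC were always named. This gave 171 genes, all well above background in both channels on all 12 arrays and none saturated.

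The lists covered MondoA and ChREBP targets, Mlx and Max network factors, glycolysis, glucose transporters, the pentose phosphate pathway, the hexosamine pathway with glycogen, lipogenesis, cholesterol synthesis, the amino acid response with ATF4 targets, aminoacyl-tRNA synthetases, endoplasmic reticulum stress with chaperones, glutamine and TCA metabolism, the hypoxia response, the NRF2 antioxidant response, G1/S with DNA replication, mitosis, ribosome biogenesis, immediate early genes, FOXO targets with autophagy, inflammatory cytokines with NF-kB, the interferon response, and nuclear genes of oxidative phosphorylation. Markers of ductal epithelium stood for the lineage of the line, and those of stromal fibroblasts and of acinar and islet cells for other pancreatic cell types. Each list was set against all other genes tested with limma's camera at a preset correlation of 0.01, adjusted over 150 tests, and again with an estimated correlation. Members that rose or fell were counted at the adjusted p over all genes, and also adjusted over the list alone.

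The 4 replicate numbers were checked for pairing. All 12 pairs of arrays with the same number had residuals correlated beyond 0.1 (Pearson r across genes 0.13 to 0.36), against a median of -0.055 and a highest value of 0.15 for unlike numbers, so a replicate block was run as an alternative. The number equals the array's position on its slide throughout, so it may stand for position as much as for culture. The arrays were scanned in 3 sessions, each holding the 4 arrays of 1 group, so group and scan session cannot be told apart. The files record 1 slide code for both the glucose and the glucose plus glutamine arrays, but the 8 arrays take each of the 4 positions more than once, so the code may be wrong and no value rests on it.

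The other alternatives were no background correction, the software's ratio, the series table, median centring in place of loess, Aquantile normalization between arrays, no filter, a filter that asks for both channels on all 12 arrays, outlying spots kept, the mean of a gene's probes, only the arrays compared, array weights, a trended and robust fit, an added limit of log2 1, fry in place of camera, and each array left out. The Cy5 channel alone was added after the data had been seen. The model fit and its threshold were tested on simulated log2 ratios of 22848 genes, drawn independently with each gene's own spread. Into these, 50 changes of each size were planted per comparison. Background correction, normalization, the filter and the choice of probe were not part of the simulation. Changes of log2 0.5 were recovered at 98% to 100% against depleted cells and 94% to 96% between groups. Changes of log2 0.25 were recovered at 76% to 82% and at 44% to 50%, with 7 to 14 false calls per comparison. Planted changes were a small part of the 22848 genes, whereas 54.7% to 71.5% of genes were called in the data. The adjusted p depends on that share, so neither the recovery nor the number of false calls carries over to the data. Data were handled with the package data.table (version 1.17.8), and plots were drawn with Python 3.11.15 and matplotlib 3.10.9.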

Results

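The study asked how glucose and glutamine, alone and together, act on the transcripts of BxPC-3 cells, with MondoA, a glucose-sensing transcription factor, and its target TXNIP at the centre of the question. Nutrient-treated cells were compared with depleted cells on 12 two-colour arrays, 4 per group, for glucose at 25 mM, glutamine at 2 mM, and glucose plus glutamine, each for 6 h. All values are log2 ratios of nutrient-treated over depleted cells, or differences of such ratios, with the SE of the limma fit and n = 4 arrays per group. This SE draws on the spread within all 3 groups. It can be smaller than the arrays of 1 group alone would give, as for TXNIP with glucose. Median signal per array was 229 to 337 in the depleted channel and 364 to 473 in the nutrient channel, and 22848 genes were tested. Across genes, arrays of 1 group correlated at Pearson r 0.812 to 0.912 for glucose, 0.937 to 0.96 for glutamine and 0.948 to 0.966 for glucose plus glutamine. Between groups r was 0.256 to 0.575. Genes are not independent replicates, so no p goes with these. Each group filled its own scan session, so nutrient and session cannot be told apart in any comparison. A change is called when the limma adjusted p is under 0.05, and with a median residual SD of 0.0769 small changes are called, so counts are also given at a size of log2 1 or more. Highest and lowest genes are those of the naming rule, with a gene symbol and a mean brightness at or over the median of the genes tested.

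In cells given glucose alone, a pair of arrestin family transcripts stood far above the rest. TXNIP, which binds thioredoxin and restrains glucose uptake, was 7.56-fold higher than in depleted cells (log2 2.92 ± 0.083 SE, n = 4, limma adjusted p = 4.2e-12), with an SD between arrays of 0.33. ARRDC4, a related arrestin domain gene, was 7.47-fold higher (log2 2.90 ± 0.044 SE, n = 4, limma adjusted p = 6.4e-15). TXNIP is read by a probe at chromosome 1, 142931491 to 142931550, and ARRDC4 by one at chromosome 15, 96317899 to 96317958 (hg17). Next came the membrane protein SLITRK6 at log2 1.68, the heat shock chaperone HSPA1A at 1.1, the guanine nucleotide exchange factor VAV3 at 1.02 and GNG11 at 1.00. TMT1A at 0.97, the aquaglyceroporin AQP3 at 0.96, the death ligand TNFSF10 at 0.95 and LFNG at 0.94 completed the 10 highest among genes with a symbol and a mean brightness at or over the median. Furthest down were the cytolinker DST at -1.92, the phosphatase PTPRR at -1.58, AKAP12 at -1.56 and HERPUD1, a component of endoplasmic reticulum-associated degradation, at -1.56. The matrix protein THBS1 and the stress factor ATF3 were both at -1.45, SH2D5 was at -1.41, KDM6A at -1.34, the Wnt antagonist DKK1 at -1.30 and EIF4A2 at -1.29. Further probes of DST moved less, by -0.33 to -0.44. By the naming rule these 20 genes had 1 sign on all 4 glucose arrays. Their SE were 0.025 to 0.083 and their limma adjusted p at most 2.5e-08.

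Among the lists, ribosome biogenesis fell in 20 of 26 measured genes with glucose alone (median log2 -0.31, camera adjusted p = 5.9e-08, adjusted p = 0.028 with an estimated correlation), for example MYBBP1A at -0.58, while median centring gave a median of 0.10 and ended the call at adjusted p = 0.905. NPM1 from this list read 0.27 on its brightest probe but -0.20 to -0.54 on further probes. Endoplasmic reticulum stress and chaperone genes fell in 17 of 23 (median -0.26, camera adjusted p = 2.3e-05, adjusted p = 0.15 with an estimated correlation), and median centring turned the median to 0.17. ERO1B was at -1.1 and SEC61B the other way at 0.42. Mitosis genes fell in 20 of 25 (median -0.28, camera adjusted p = 1e-05, adjusted p = 0.37 with an estimated correlation), and median centring turned the median to 0.09. UBE2C was at -0.82 and CDK1 at -0.68 against AURKB at 0.13. G1/S and DNA replication genes rose in 19 of 25 (median 0.20, camera adjusted p = 0.0013, adjusted p = 0.38 with an estimated correlation). E2F2 was at 0.94 and CCNE2 at 0.61 against CDT1 at -0.54. Inflammatory cytokines and NF-kB genes fell in 12 of 20 (median -0.23, camera adjusted p = 0.0024, adjusted p = 0.22 with an estimated correlation). TNFAIP3 was at -1.06 and IL1A at -0.84 against CXCL1 at 0.52. The hexosamine and glycogen genes fell in 9 of 15 (median -0.19, camera adjusted p = 0.032, adjusted p = 0.28 with an estimated correlation and adjusted p = 0.0547 with the replicate block), and median centring turned the median to 0.17. PPP1R3B was at -1.01 and UAP1 at -0.54 against GFPT2 at 0.45. That call also ended with the software's ratio (adjusted p = 0.0986), the stricter filter (adjusted p = 0.0611), the mean of a gene's probes (adjusted p = 0.0616) and a fit to only the arrays compared (adjusted p = 0.0543).

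The list of MondoA and ChREBP targets did not pass its threshold in any of the 6 comparisons. With glucose alone 6 of its 16 measured members rose and 4 fell, with a median of -0.01 and a mean of 0.29 (camera adjusted p = 0.89), and TXNIP and ARRDC4 were its only members higher by log2 1 or more. HK2, the first enzyme of glycolysis and also on this list, was at -0.82. Of the other genes named in every comparison, the asparagine synthetase gene ASNS was at 0.74, DDIT3 at -1.08, MYC at -0.86 and the chaperone HSPA5 at -0.65. Median centring moved MYC to -0.03 and HSPA5 to -0.06 and ended both calls. The glucose transporter SLC2A1 was at -0.15 ± 0.033 (SE, n = 4, limma adjusted p = 0.00094), and at 0.61 under median centring.

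With glucose alone limma called 13111 genes, 57.4% of those tested, with 6772 higher and 6339 lower, and of these 10 were higher and 55 lower by log2 1 or more. Median centring, which leaves an intensity trend in the ratios, moved the median of all genes from 0.01 to 0.14 with glucose, from 0.02 to 0.11 with glutamine and from 0.01 to 0.18 with both. Under it the brightest 25% of genes had medians of 0.41, 0.32 and 0.57, against -0.02, -0.03 and -0.06 after loess. The split of the glucose calls into higher and lower rests on that choice, as median centring gave 12128 higher and 4837 lower.

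**Figure D1:**
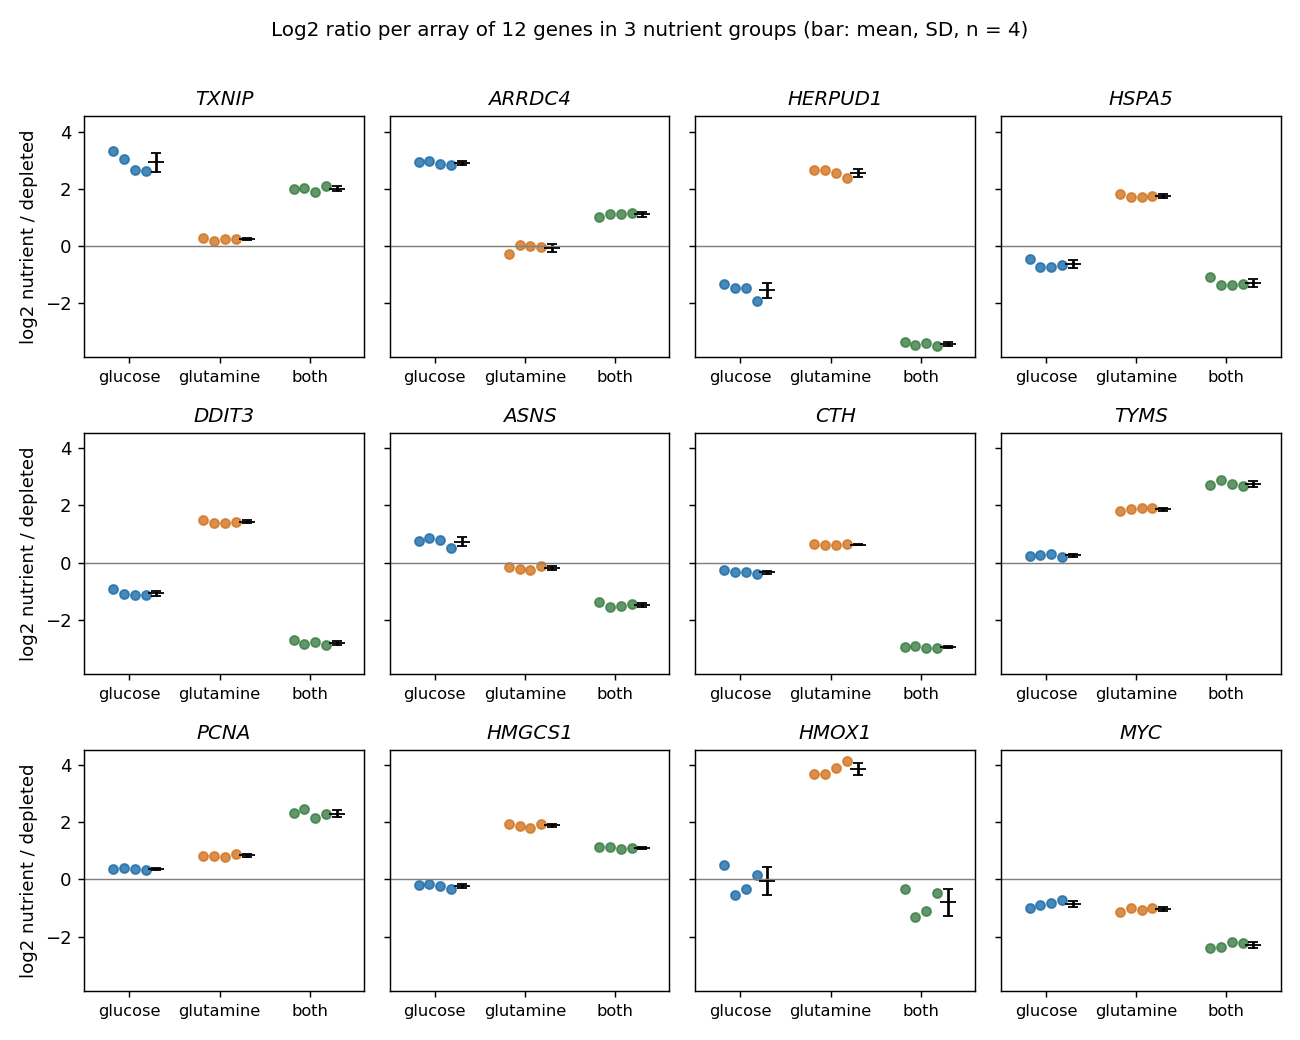
Log2 ratio of nutrient-treated over depleted cells (vertical axis) for 12 genes in the glucose, glutamine and glucose plus glutamine groups (horizontal axis), where each point is an array and the bar and whisker are the mean and SD of the 4 arrays. TXNIP lay at 2.92 with glucose, 0.24 with glutamine and 2.00 with both, while HERPUD1 lay at -1.56, 2.56 and -3.43.

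In cells given glutamine alone, a heme oxygenase and a heat shock chaperone stood highest. The heme oxygenase HMOX1, an enzyme of heme breakdown, was 14.6-fold higher (log2 3.86 ± 0.166 SE, n = 4, limma adjusted p = 3.3e-11), read by a probe at chromosome 22, 34114676 to 34114735. The heat shock chaperone HSPA6 was 10.6-fold higher (log2 3.40 ± 0.177 SE, n = 4, limma adjusted p = 2.5e-10). The chemokine CXCL1 was at 2.93, the immediate early factor EGR1 at 2.84, the sterol carrier STARD4 at 2.70 and the iron-binding lipocalin LCN2 at 2.64. HERPUD1 was at 2.56 (probe at chromosome 16, 55535201 to 55535260), CXCL14 at 2.55, ZFAND2A at 2.31 and the secretory cell factor BHLHA15 at 2.30. Furthest down were the enzymes that attach and remove O-linked N-acetylglucosamine, OGT at -2.13 and OGA at -1.94, although a further OGT probe read 0 (limma adjusted p = 0.91). IL33 and ARNT2 were both at -1.79, RFLNB at -1.65, IPO7, KMT5B and DST each at -1.62, HAS2, which makes hyaluronan, at -1.59 and ZNF750 at -1.55. By the naming rule these 20 genes had 1 sign on all 4 glutamine arrays, and their limma adjusted p was at most 5.1e-08.

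TXNIP was at 0.24 ± 0.083 with glutamine (SE, n = 4, limma adjusted p = 0.02), and its call was lost with the software's ratio (0.20, adjusted p = 0.103), without glutamine replicate 1 (adjusted p = 0.0678) and without glutamine replicate 3 (adjusted p = 0.0509). ARRDC4 was at -0.08 and was not called (limma adjusted p = 0.13), nor was HK2 at 0.02 (limma adjusted p = 0.73), for which a further probe read -0.38. DDIT3 was at 1.43, HSPA5 at 1.75, SLC2A1 at 0.24, and MYC at -1.04, with a dim further MYC probe at 0.21. ASNS was at -0.19, and at 0.56 under median centring.

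Endoplasmic reticulum stress and chaperone genes rose in 22 of 23 with glutamine alone, or 23 adjusted over the list alone, 13 of them by log2 1 or more (median 1.23, camera adjusted p = 2.5e-10, adjusted p = 0.056 with an estimated correlation). MANF was at 2.11 and HSP90B1 at 1.27. Cholesterol synthesis genes rose in 24 of 25 (median 0.90, camera adjusted p = 2.5e-10, adjusted p = 0.034 with an estimated correlation). HMGCS1, an early enzyme of the pathway, was at 1.89 and SC5D the other way at -0.43. Lipogenesis genes rose in 13 of 17 (median 0.46, camera adjusted p = 0.0054, adjusted p = 0.083 with an estimated correlation). SCD was at 1.34 and FADS1 at 1.05 against GPAM at -0.61. G1/S and DNA replication genes rose in 24 of 25 (median 0.84, camera adjusted p = 3.1e-10, adjusted p = 0.11 with an estimated correlation). CDC45 and TYMS were both at 1.87. Nuclear genes of oxidative phosphorylation rose in 26 of 29 and none fell (median 0.40, camera adjusted p = 2e-07, adjusted p = 0.059 with an estimated correlation). COX6C was at 0.92 and CYCS at 0.77. Glycolysis genes rose in 12 of 17 (median 0.17, camera adjusted p = 0.021, adjusted p = 0.16 with an estimated correlation and adjusted p = 0.0628 with the mean of a gene's probes). ALDOC was at 0.49 and TPI1 at 0.48 against ENO2 at -0.22. Glutamine and TCA genes rose in 21 of 35 (median 0.15, camera adjusted p = 0.046, adjusted p = 0.12 with an estimated correlation). GOT1 was at 0.95 and IDH1 at 0.82 against GLUD2 at -0.57. That call also ended with the replicate block (adjusted p = 0.0588), the stricter filter (adjusted p = 0.0611), a fit to only the arrays compared (adjusted p = 0.0597) and without glutamine replicate 1 (adjusted p = 0.0527).

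Inflammatory cytokines and NF-kB genes rose in 16 of 20 with glutamine (median 0.48, camera adjusted p = 0.00053, adjusted p = 0.16 with an estimated correlation). CXCL8 was at 2.23 and CXCL2 at 1.93 against RELB at -0.82. Genes of the NRF2 antioxidant response rose in 15 of 18 (median 0.42, camera adjusted p = 0.00095, adjusted p = 0.22 with an estimated correlation). GCLM, a subunit of the ligase that makes the precursor of glutathione, was at 1.17, while FTL was at -0.20 and at 0.51 under median centring. Immediate early genes rose in 17 of 25 (median 0.42, camera adjusted p = 0.027, adjusted p = 0.42 with an estimated correlation). FOS was at 3.00. The software's ratio (adjusted p = 0.0583), the stricter filter (adjusted p = 0.0697) and a fit to only the arrays compared (adjusted p = 0.0523) each ended that call. FOXO targets and autophagy genes fell in 17 of 26 (median -0.21, camera adjusted p = 0.027, adjusted p = 0.08 with an estimated correlation), and median centring ended the call at adjusted p = 0.0752. ATG14 was at -0.57 and FBXO32 at -0.52 against WIPI1 at 1.1. Mitosis genes fell in 18 of 25 (median -0.17, camera adjusted p = 0.0053, adjusted p = 0.54 with an estimated correlation), and median centring turned the median to 0.03. TOP2A was at -0.65 and PLK1 at -0.38 against AURKB at 0.60. The amino acid response rose in 22 of 37 and fell in 9, or 11 adjusted over the list alone (median 0.16, camera adjusted p = 0.049, adjusted p = 0.24 with an estimated correlation and adjusted p = 0.0565 with the replicate block). CHAC1 from this list was at 0.89 and PHGDH at -0.36. The software's ratio lowered the median to 0.09 and ended that call (adjusted p = 0.124), as did the stricter filter (adjusted p = 0.0746), a fit to only the arrays compared (adjusted p = 0.0686), array weights (adjusted p = 0.0546) and no background correction (adjusted p = 0.0528). Against depleted cells limma called 16329 genes with glutamine, 71.5% of those tested, with 8750 higher and 7579 lower, of which 331 and 114 by log2 1 or more. Median centring gave 11369 higher and 4805 lower.

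With glucose plus glutamine, TYMS stood highest and HERPUD1 lowest. TYMS, the thymidylate synthase, was 6.74-fold higher (log2 2.75 ± 0.035 SE, n = 4, limma adjusted p = 1.6e-16), read by a probe at chromosome 18, 663276 to 663335. Behind it were E2F2 at 2.35, CDC45 at 2.31, the polymerase clamp PCNA at 2.30, MCM10 at 2.16, DSCC1 at 2.13, the aldo-keto reductase AKR1B10 at 2.09, DTL at 2.06, CDKN2C at 2.04 and HELLS at 2.00. HERPUD1 was 10.8-fold lower (log2 -3.43 ± 0.071 SE, n = 4, limma adjusted p = 1.1e-14). The stress factors ATF3 and DDIT3 were at -3.35 and -2.80, the cysteine-making enzyme CTH at -2.96, the pseudokinase TRIB3 at -2.91 and ERRFI1 at -2.81. The growth factor AREG was at -2.70, CREBRF at -2.69, GDF15 at -2.61 and the unfolded protein response factor XBP1 at -2.53. These 20 genes had limma adjusted p of at most 9.1e-14. TXNIP was at 2.00 ± 0.083 (SE, n = 4, limma adjusted p = 1.3e-11) and ARRDC4 at 1.1 ± 0.044 (SE, n = 4, limma adjusted p = 8.2e-12). ASNS was at -1.48, HSPA5 at -1.29, HK2 at -1.01 and MYC at -2.29, and SLC2A1 at 0.04 was not called (limma adjusted p = 0.34).

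All 25 measured G1/S and DNA replication genes rose with both nutrients, 21 by log2 1 or more (median 1.48, camera adjusted p = 1.4e-15, adjusted p = 0.056 with an estimated correlation). Amino acid response genes fell in 35 of 37, 22 by log2 1 or more (median -1.24, camera adjusted p = 3.3e-15, adjusted p = 0.0041 with an estimated correlation). ATF5 the other way was at 0.23. Aminoacyl-tRNA synthetases fell in 14 of 20 (median -0.64, camera adjusted p = 0.0018, adjusted p = 0.034 with an estimated correlation), and median centring turned the median to 0.29. AARS1 was at -1.24 and CARS at -1.12 against VARS1 at 0.45. Endoplasmic reticulum stress and chaperone genes fell in 19 of 23 (median -0.50, camera adjusted p = 1.7e-05, adjusted p = 0.15 with an estimated correlation), and median centring turned the median to 0.28. SEC61B the other way was at 0.49. Cholesterol synthesis genes rose in 22 of 25 (median 0.64, camera adjusted p = 1e-07, adjusted p = 0.053 with an estimated correlation). ACAT2 was at 1.18, while SC5D was at -0.15 and at 0.25 under median centring. Nuclear genes of oxidative phosphorylation rose in 28 of 29 (median 0.31, camera adjusted p = 1.3e-07, adjusted p = 0.058 with an estimated correlation). UQCRQ was at 0.88. Glutamine and TCA genes rose in 26 of 35 (median 0.27, camera adjusted p = 0.00095, adjusted p = 0.034 with an estimated correlation). IDH2 was at 0.81 and IDH1 at 0.72, and the glutamine transporter SLC1A5 the other way at -0.97. Glycolysis genes rose in 14 of 17 (median 0.31, camera adjusted p = 0.0039, adjusted p = 0.095 with an estimated correlation). PGAM1 was at 0.69 and TPI1 at 0.61.

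Immediate early genes fell in 23 of 25 with both nutrients (median -0.53, camera adjusted p = 3.1e-07, adjusted p = 0.089 with an estimated correlation). KLF4 was at -1.49 and FOS the other way at 0.34. FOXO targets and autophagy genes fell in 19 of 26 (median -0.58, camera adjusted p = 0.00011, adjusted p = 0.028 with an estimated correlation). The insulin receptor substrate IRS2 was at -1.83 and FBXO32 at -1.40 against SESN1 at 0.59. Inflammatory cytokines and NF-kB genes fell in 12 of 20 (median -0.48, camera adjusted p = 0.012, adjusted p = 0.32 with an estimated correlation). IL1A was at -1.90 and IL1B at -1.46 against CXCL1 at 1.32. Mlx and Max network factors fell in 8 of 13 (median -0.49, camera adjusted p = 0.02, adjusted p = 0.08 with an estimated correlation and adjusted p = 0.0611 with the stricter filter), and median centring turned the median to 0.08. MXI1 was at -0.73 against MXD3 at 0.17. Interferon response genes fell in 11 of 16 (median -0.34, camera adjusted p = 0.044, adjusted p = 0.54 with an estimated correlation and adjusted p = 0.0547 with the replicate block), and median centring turned the median to 0.13. RSAD2 was at -1.47 and IFIT2 at -1.29 against IFI44 at 0.85. Leaving out replicate 3 or 4 of glucose plus glutamine also ended that call (adjusted p = 0.0504 and 0.0514), as did the software's ratio, the stricter filter and the mean of a gene's probes (adjusted p = 0.0611, 0.0758 and 0.062). Hexosamine and glycogen genes fell in 10 of 15, or 11 adjusted over the list alone (median -0.35, camera adjusted p = 0.044, adjusted p = 0.31 with an estimated correlation and adjusted p = 0.0566 with the replicate block), and median centring turned the median to 0.14. PPP1R3B was at -1.17 and OGA at -0.76 against PGM1 at 0.62. The same 3 alternatives ended this call (adjusted p = 0.0759, 0.0758 and 0.0544). In all, limma called 15984 genes, 70% of those tested, with 8113 higher and 7871 lower, of which 372 and 424 by log2 1 or more. Median centring gave 12640 higher and 5771 lower.

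**Figure D2:**
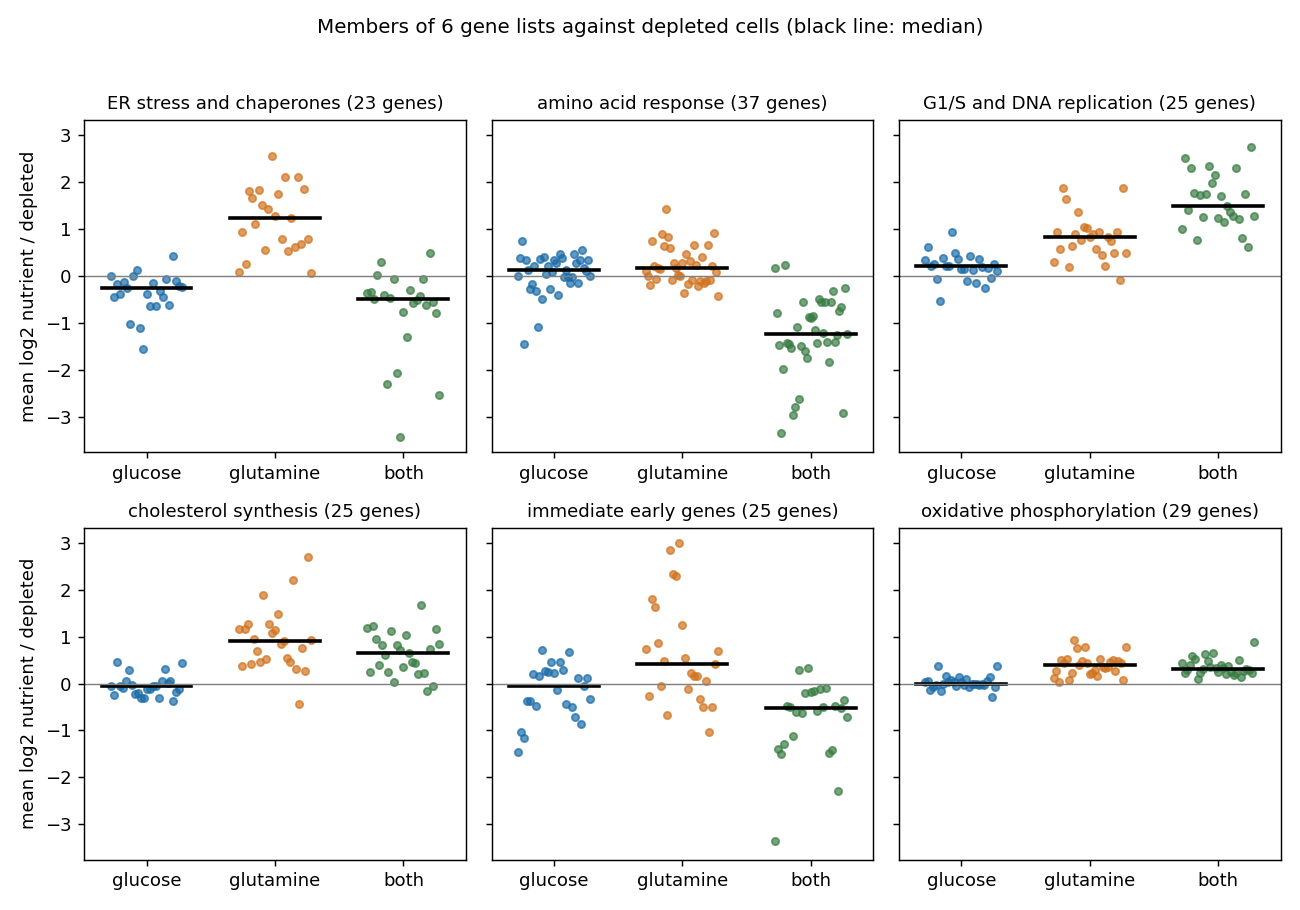
Log2 ratio over depleted cells (vertical axis) of each measured member of 6 gene lists in the 3 nutrient groups (horizontal axis), where each point is the mean of 4 arrays for a gene and the black line is the list's median. The endoplasmic reticulum list had medians of -0.26 with glucose, 1.23 with glutamine and -0.50 with both, of which median centring turned the first and the last to 0.17 and 0.28, and the G1/S list had 0.20, 0.84 and 1.48.

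Glucose plus glutamine was then compared with glucose alone, which asks what glutamine changed in cells that had glucose. TXNIP was lower with glutamine present, at -0.92 ± 0.118 (SE, n = 4 per group, limma adjusted p = 9.3e-06), and so was ARRDC4, at -1.80 ± 0.062 (SE, n = 4 per group, limma adjusted p = 1.2e-11). TYMS was higher by 2.50 ± 0.049 (SE, n = 4 per group, limma adjusted p = 1.2e-13), followed by CDC45 at 2.05, FGFBP1 at 1.99, MNS1 at 1.97, the polymerase subunit POLE2 and PCNA both at 1.94, DSCC1 at 1.93, CDC6 and the protocadherin PCDH7 both at 1.84, and MCM10 at 1.80. Further PCDH7 probes read 0.97 and 0.29 here, and the latter read -0.44 with both nutrients against depleted cells, where the chosen probe read 1.77. Lowest were TRIB3 at -3.01, CTH at -2.63, ATF4, the factor that drives the amino acid response, at -2.32, XBP1 at -2.29 and ASNS at -2.21. ERRFI1 at -2.15, GDF15 at -2.13, AREG at -2.05, CREBRF at -1.92 and ATF3 at -1.90 followed. By the naming rule the arrays of both groups did not overlap in these 20 genes, and their limma adjusted p was at most 5.9e-11. A further ATF4 probe read -0.18 with glucose alone against depleted cells, where the chosen probe read 0.33. DDIT3 was at -1.73, HSPA5 at -0.64 with a further probe at 0.29, MYC at -1.43, SLC2A1 at 0.19 and HK2 at -0.19. Of these, HK2 lost its call under median centring (limma adjusted p = 0.985) and with the mean of its probes (limma adjusted p = 0.363), and HSPA5 with the mean of its probes (limma adjusted p = 0.0986). SLC2A1 lost its call in the Cy5 channel alone (limma adjusted p = 0.0981).

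All 25 G1/S and DNA replication genes were higher than with glucose alone, 23 by log2 1 or more (median 1.34, camera adjusted p = 3.2e-21, adjusted p = 0.034 with an estimated correlation). Of the amino acid response genes 35 of 37 were lower, 26 by log2 1 or more (median -1.26, camera adjusted p = 1.1e-21, adjusted p = 0.0019 with an estimated correlation). JDP2 was at -1.81 and ALDH18A1 the other way at 0.17. Cholesterol synthesis genes were higher in 24 of 25 (median 0.70, camera adjusted p = 2.1e-11, adjusted p = 0.03 with an estimated correlation). HMGCS1 was at 1.34 and ACAT2 at 1.23 against SC5D at -0.20. All 29 nuclear genes of oxidative phosphorylation were higher (median 0.29, camera adjusted p = 9.5e-09, adjusted p = 0.052 with an estimated correlation). CYCS was at 0.70 and ATP5MC1 at 0.49. Glutamine and TCA genes were higher in 26 of 35 (median 0.34, camera adjusted p = 9.8e-07, adjusted p = 0.011 with an estimated correlation). IDH2 was at 0.76 and FH at 0.57 against SLC1A5 at -0.77. Glycolysis genes were higher in 13 of 17 (median 0.30, camera adjusted p = 0.00028, adjusted p = 0.056 with an estimated correlation). LDHA was at 0.96 and PGAM1 at 0.57. Ribosome biogenesis genes were higher in 15 of 26 (median 0.14, camera adjusted p = 0.00047, adjusted p = 0.059 with an estimated correlation). NOP56 was at 0.96 and MYBBP1A at 0.53 against RRN3 at -0.17. A further NOP56 probe read -0.23 with glutamine alone against depleted cells, where the chosen probe read 0.52. Mitosis genes were higher in 16 of 25, or 17 adjusted over the list alone (median 0.30, camera adjusted p = 0.0033, adjusted p = 0.52 with an estimated correlation). CDK1 was at 0.97 and AURKB at 0.75 against CENPA at -0.33.

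Lists with lower members in this comparison included FOXO targets and autophagy, lower in 19 of 26 (median -0.65, camera adjusted p = 5e-08, adjusted p = 0.0044 with an estimated correlation). GABARAPL1 was at -1.34 and HBP1 at -1.25 against SESN3 at 0.32. Immediate early genes were lower in 21 of 25 and none was higher (median -0.48, camera adjusted p = 2.7e-09, adjusted p = 0.058 with an estimated correlation). KLF4 was at -0.99. Mlx and Max network factors were lower in 7 of 13, or 8 adjusted over the list alone (median -0.29, camera adjusted p = 0.0036, adjusted p = 0.052 with an estimated correlation). MXI1 was at -0.69 against MXD3 at 0.14. The MXD3 value was -0.03 in the Cy5 channel alone, and leaving out replicate 3 or 4 of glucose, or 1 or 2 of glucose plus glutamine, raised its limma adjusted p to 0.0564 to 0.0712. Endoplasmic reticulum stress and chaperone genes were lower in 15 of 23 (median -0.20, camera adjusted p = 0.0051, adjusted p = 0.33 with an estimated correlation). HERPUD1 was at -1.88 against DERL3 at 0.42. Interferon response genes were lower in 10 of 16 (median -0.24, camera adjusted p = 0.0063, adjusted p = 0.42 with an estimated correlation). RSAD2 was at -1.30 and IFIT2 at -0.96 against IFI44 at 0.84. Aminoacyl-tRNA synthetases were lower in 12 of 20 (median -0.53, camera adjusted p = 0.017, adjusted p = 0.07 with an estimated correlation and adjusted p = 0.0589 in the Cy5 channel alone). GARS1 was at -1.42 and CARS at -1.24 against FARSB at 0.54. The comparison called 12489 genes with limma, 54.7% of those tested, with 6080 higher and 6409 lower, of which 234 and 180 by log2 1 or more. Median centring gave 7602 higher and 3997 lower.

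Glucose plus glutamine against glutamine alone shows what glucose changed in cells that had glutamine. HERPUD1 was 63.5-fold lower with glucose present (log2 -5.99 ± 0.101 SE, n = 4 per group, limma adjusted p = 6.4e-15), and HMOX1 was at -4.67, DDIT3 at -4.23, ZNF165 at -4.17 and the endoplasmic reticulum co-chaperone DNAJB9 at -4.15. VAV3 was at 2.05, BMP7 at 2.03, SLITRK6 at 1.89, TXNIP at 1.76 ± 0.118 (SE, n = 4 per group, limma adjusted p = 9.9e-09) and ANP32D at 1.59. ARRDC4 was at 1.18, HSPA5 at -3.04, ASNS at -1.28, MYC at -1.25, HK2 at -1.03, and SLC2A1 at -0.20, or 0.14 under median centring. All 23 endoplasmic reticulum stress and chaperone genes were lower, 18 by log2 1 or more (median -1.66, camera adjusted p = 1.6e-16, adjusted p = 0.03 with an estimated correlation). Amino acid response genes were lower in 35 of 37, 22 by log2 1 or more (median -1.28, camera adjusted p = 4.3e-20, adjusted p = 0.0019 with an estimated correlation). CTH was at -3.59. G1/S genes were higher in 24 of 25, or 25 adjusted over the list alone (median 0.78, camera adjusted p = 2.4e-14, adjusted p = 0.059 with an estimated correlation). E2F2 was at 1.58 and PCNA at 1.46. Immediate early genes were lower in 23 of 25 (median -1.15, camera adjusted p = 2e-13, adjusted p = 0.034 with an estimated correlation). ATF3 was at -4.08 and CCN2 at -3.31. Inflammatory cytokines and NF-kB genes were lower in 18 of 20 (median -1.11, camera adjusted p = 7.5e-11, adjusted p = 0.034 with an estimated correlation). CXCL2 was at -3.39 and CXCL3 at -2.20 against NFKBIA at 0.52. Interferon response genes were lower in 14 of 16 (median -0.47, camera adjusted p = 1.3e-05, adjusted p = 0.23 with an estimated correlation). IFI6 was at -1.98 and IFITM1 at -1.03. Mitosis genes were higher in 16 of 25 (median 0.24, camera adjusted p = 0.014, adjusted p = 0.6 with an estimated correlation). CCNA2 was at 0.55 and KIF11 at 0.38 against UBE2C at -0.33.

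The remaining lists past their threshold against glutamine alone each lost the call with at least 1 alternative besides the estimated correlation. Cholesterol synthesis genes were lower in 15 of 25 (median -0.22, camera adjusted p = 0.00068, adjusted p = 0.15 with an estimated correlation and adjusted p = 0.31 under median centring). STARD4 was at -1.54 and HMGCS1 at -0.78 against SC5D at 0.28. Aminoacyl-tRNA synthetases were lower in 15 of 20 (median -0.36, camera adjusted p = 0.00095, adjusted p = 0.034 with an estimated correlation, adjusted p = 0.0791 under median centring and adjusted p = 0.0653 in the Cy5 channel alone). GARS1 was at -1.45 and AARS1 at -1.35 against RARS1 at 0.31. FOXO targets and autophagy genes were lower in 17 of 26 (median -0.38, camera adjusted p = 0.0039, adjusted p = 0.044 with an estimated correlation and adjusted p = 0.0608 in the Cy5 channel alone). WIPI1 was at -2.23 and IRS2 at -1.83 against SESN1 at 1.1. NRF2 antioxidant genes were lower in 12 of 18 (median -0.29, camera adjusted p = 0.01, adjusted p = 0.33 with an estimated correlation and adjusted p = 0.121 under median centring). The cystine transporter SLC7A11 was at -1.93 and TXNRD1 at -1.30 against AKR1B10 at 1.22. Mlx and Max network factors were lower in 8 of 13 (median -0.29, camera adjusted p = 0.035, adjusted p = 0.11 with an estimated correlation and adjusted p = 0.0611 with the software's ratio), and median centring turned the median to 0.03. MXD1 was at -1.12 against MXD4 at 0.16. Lipogenesis genes were lower in 12 of 17, or 13 adjusted over the list alone (median -0.27, camera adjusted p = 0.048, adjusted p = 0.2 with an estimated correlation and adjusted p = 0.0547 with the replicate block). LPIN1 was at -0.98 and ACSL3 at -0.57 against GPAM at 0.78. Leaving out glucose plus glutamine replicate 3 (adjusted p = 0.0504) or glutamine replicate 2 (adjusted p = 0.0623) ended that call, as did median centring (adjusted p = 0.31) and the Cy5 channel alone (adjusted p = 0.301). The mean of a gene's probes moved the median to -0.16 and ended it too (adjusted p = 0.0866), and so did the stricter filter (adjusted p = 0.0756), the software's ratio (adjusted p = 0.0566), no background correction (adjusted p = 0.0536) and the trended and robust fit (adjusted p = 0.0507). Here limma called 13716 genes, 60% of those tested, with 6512 higher and 7204 lower, of which 125 and 444 by log2 1 or more. Median centring gave 9429 higher and 5624 lower.

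Set directly against glutamine alone, glucose alone gave higher ARRDC4 at 2.98 ± 0.062 and TXNIP at 2.68 ± 0.118 (SE, n = 4 per group, limma adjusted p = 1.3e-13 and 1.3e-10). SLITRK6 at 2.09, RFLNB at 1.97 and OGA at 1.95 were the next highest. HSPA6 at -4.29, HERPUD1 at -4.11, HMOX1 at -3.91, BHLHA15 at -3.42 and ZNF165 at -3.16 were the lowest. Of the remaining genes named throughout, ASNS was at 0.93, DDIT3 at -2.50, HSPA5 at -2.39, HK2 at -0.84 and SLC2A1 at -0.39. MYC was at 0.18 (limma adjusted p = 0.022), a call lost with the software's ratio (limma adjusted p = 0.205), with the mean of its probes (limma adjusted p = 0.603) and when glucose replicate 3 or 4 or glutamine replicate 1 or 3 was left out (limma adjusted p 0.0513 to 0.0747). Endoplasmic reticulum stress and chaperone genes were lower in 22 of 23 (median -1.53, camera adjusted p = 1.2e-13, adjusted p = 0.034 with an estimated correlation). HSP90B1 was at -1.66. Cholesterol synthesis genes were lower in 24 of 25 (median -0.90, camera adjusted p = 2.3e-12, adjusted p = 0.03 with an estimated correlation). STARD4 was at -2.82 and HMGCS1 at -2.12 against SC5D at 0.49. G1/S genes were lower in 22 of 25 (median -0.55, camera adjusted p = 1.9e-08, adjusted p = 0.15 with an estimated correlation). CDC6 was at -1.72 and CDC45 at -1.61 against E2F2 at 0.17. Inflammatory cytokines and NF-kB genes were lower in 17 of 20 (median -0.90, camera adjusted p = 4.8e-08, adjusted p = 0.056 with an estimated correlation). CXCL2 was at -2.80 and CXCL3 at -2.03. Nuclear genes of oxidative phosphorylation were lower in 28 of 29 (median -0.33, camera adjusted p = 1e-07, adjusted p = 0.058 with an estimated correlation). CYCS was at -0.82. Glutamine and TCA genes were lower in 26 of 35 (median -0.27, camera adjusted p = 0.00022, adjusted p = 0.03 with an estimated correlation). GOT1 was at -0.74 and FH at -0.62.

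Ribosome biogenesis genes were also lower with glucose than with glutamine, in 20 of 26 (median -0.23, camera adjusted p = 0.00022, adjusted p = 0.056 with an estimated correlation). MYBBP1A was at -0.79 and BOP1 at -0.74 against DKC1 at 0.21. NOP56, counted as lower at -0.53, read 0.16 on a further probe. Immediate early genes were lower in 17 of 25 (median -0.67, camera adjusted p = 0.0012, adjusted p = 0.26 with an estimated correlation). CCN2 was at -2.97 and ATF3 at -2.19 against DUSP6 at 0.84. Lipogenesis genes were lower in 13 of 17 (median -0.48, camera adjusted p = 0.0041, adjusted p = 0.08 with an estimated correlation). SCD was at -1.21 and SREBF1 at -0.89 against GPAM at 0.88. NRF2 antioxidant genes were lower in 13 of 18 (median -0.42, camera adjusted p = 0.0041, adjusted p = 0.29 with an estimated correlation). PIR was at -0.58 against AKR1C1 at 0.33. A further AKR1C1 probe read -0.18, and the AKR1C1 call was lost with the mean of its probes (limma adjusted p = 0.0622) and in the Cy5 channel alone (limma adjusted p = 0.105). Glycolysis genes were lower in 12 of 17 (median -0.17, camera adjusted p = 0.015, adjusted p = 0.15 with an estimated correlation, adjusted p = 0.28 under median centring and adjusted p = 0.078 in the Cy5 channel alone). PFKM was at -0.58. FOXO targets and autophagy genes were higher in 16 of 26, or 18 adjusted over the list alone (median 0.16, camera adjusted p = 0.027, adjusted p = 0.08 with an estimated correlation). TP53INP1 was at 1.49 and SESN1 at 0.94 against WIPI1 at -1.33. In this comparison limma called 13771 genes, 60.3% of those tested, with 6410 higher and 7361 lower, of which 129 and 337 by log2 1 or more.

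**Figure D3:**
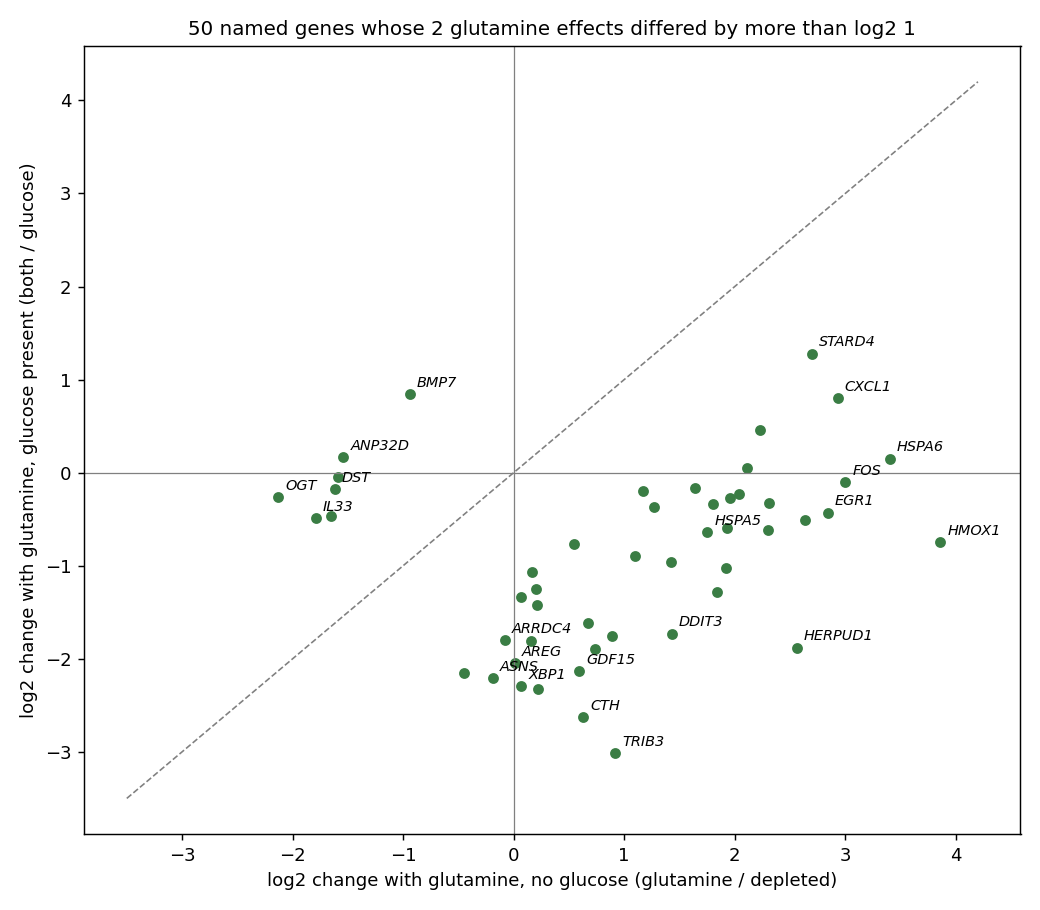
Effect of glutamine in cells without glucose (horizontal axis, log2 of glutamine over depleted) and in cells with glucose (vertical axis, log2 of glucose plus glutamine over glucose), where each point is 1 of 50 named genes whose interaction passed a limma test against a margin of log2 1 and the dashed line marks equal effects. HMOX1 lay at 3.86 and -0.75, HERPUD1 at 2.56 and -1.88, and BMP7 at -0.94 and 0.84, while OGT, at -2.13 and -0.26 on its brightest probe, had 0 and -0.04 on a further one.

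Whether glutamine acted alike with and without glucose was tested as an interaction. For ARRDC4 the glutamine effect was -0.08 without glucose and -1.80 with it, an interaction of -1.73 ± 0.076. For TXNIP the interaction was -1.16 ± 0.144 (SE, limma adjusted p = 9.8e-06). For ASNS the glutamine effect was -0.19 and -2.21, for CTH 0.63 and -2.63, and for TRIB3 0.92 and -3.01. DDIT3 went from 1.43 to -1.73 and HSPA5, on its chosen probe, from 1.75 to -0.64. In cells with glucose a further HSPA5 probe read 0.29, and the mean of the HSPA5 probes gave -0.178 (limma adjusted p = 0.0986). The interaction passed the threshold in 12460 genes with limma, 54.5% of those tested, with 5873 positive and 6587 negative, and in 218 genes its size was past log2 1 in a limma test against that margin, 196 of them negative and 22 positive. A gene-specific dye effect stays in the interaction, unlike in the comparisons between groups.

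Across the 25 lists and 6 comparisons, 72 of 150 tests passed the threshold with the preset correlation, and 20 of these also with an estimated one. Counts adjusted over the list alone equalled those over all genes in 126 of the 150 tests. Besides the MondoA and ChREBP targets, glucose transporters (11 measured), the pentose phosphate pathway (11), the hypoxia response (20), and markers of ductal epithelium (12), stromal fibroblasts (9) and acinar and islet cells (4) passed in none of the 6 comparisons. With glutamine alone 7 of the 11 glucose transporters rose and 1 fell (camera adjusted p = 0.15), and 13 of the 20 hypoxia genes rose and 7 fell (camera adjusted p = 0.21). With both nutrients 5 of the 11 pentose phosphate genes rose, or 4 adjusted over the list alone, and 1 fell (camera adjusted p = 0.3). Ductal markers rose in 6 of 12 with glucose and fell in 3 (camera adjusted p = 0.36), stromal markers rose in 4 of 9 and fell in 3 (camera adjusted p = 0.8), and acinar and islet markers rose in 2 of 4 (camera adjusted p = 0.35).

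A few members named as examples lost their call under an alternative. Under median centring these were OGA with both nutrients (limma adjusted p = 0.565), PLK1 with glutamine (0.686), RRN3 in both against glucose (0.331), SC5D in both against glucose (0.247) and UBE2C in both against glutamine (0.895). With the mean of a gene's probes they were FTL with glutamine (limma adjusted p = 0.116), MXD4 in both against glutamine (0.148) and E2F2 in glucose against glutamine (0.199). In the Cy5 channel alone they were SC5D in both against glucose (limma adjusted p = 0.0889) and MXD4 in both against glutamine (0.809).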

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

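Chosen only after the result was seen were the Cy5 channel alone, the 2 tests of the endoplasmic reticulum pattern, the test of a dye effect bound to the labelled transcript, and the log2 1 margin for the interaction. The bound for Cy5 alone in the next paragraph was written before its share was computed. The others were set beforehand.

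Genes that differed between nutrient groups by log2 1 or more numbered 414 for glucose plus glutamine against glucose, 569 against glutamine, and 466 for glucose against glutamine. If the depleted RNA in the Cy3 channel had differed between slides, less than 0.5 of the ratio difference should be seen in Cy5 alone. The median share seen in Cy5 alone was 1, 0.98 and 1, with lower quartiles of 0.935, 0.881 and 0.926, which argues against the depleted RNA as the source for most of these genes. Scan session stays open, as each session held 1 group, and so does the nutrient itself, which the design names.

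In 6142 of 22848 genes the ratio to depleted cells passed the threshold in the same direction in all 3 nutrient groups, 3062 higher and 3080 lower. Independent calls would give 921 and 724, while simulated arrays with no effect gave 0 with own depleted RNA and 1909 with 1 shared depleted pool. A dye effect bound to the probe would not be shared by another probe of the gene, yet in 2037 genes with a further probe the mean ratios correlated across genes at Spearman rho 0.735 (95% bootstrap interval 0.711 to 0.757), which argues against it as the whole source. The sign of the mean ratio was shared by both probes in 84.1% of genes with a further probe, and not in the rest. A dye effect bound to the labelled transcript cannot be told apart from a response to any nutrient, because 0 arrays had the dyes exchanged. A response that all 3 media share stays open too.

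Endoplasmic reticulum stress and chaperone genes were higher with glutamine alone (camera adjusted p = 0.056 with an estimated correlation) and lower with glucose plus glutamine (camera adjusted p = 0.15 with an estimated correlation), although median centring turned the latter median to 0.276. A gene-specific dye effect stands alike in both ratios by construction and was not tested. A difference of depleted RNA between slides is argued against by the Cy5 channel alone, where the median difference of the 23 measured members between these groups was -1.56 (upper quartile -0.84) against -1.66 for the ratios. Slide and scan session of the glutamine arrays cannot be told apart from glutamine itself, as the most groups a session held was 1. The glutamine arrays did stand apart in the green channel. Their median background was 62 to 68 and their median signal 304 to 337, against 35 to 39 and 229 to 279 on the other arrays. The nutrients themselves, which the design names, stay open too.

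Other ways to divide the arrays were counted. Between groups, 1 of 35 splits of 8 arrays, the real one, gave as many genes in each of the 3 comparisons. As the replicate numbers pair the arrays, only the 8 splits that part all pairs of like number compare with the real one, too few for a share under 0.05. The real counts were 12489 for glucose plus glutamine against glucose, 13716 against glutamine and 13771 for glucose against glutamine, and limma called 0 genes in each other split. At an unadjusted p under 0.05 the highest of the other splits called 3525, 3932 and 4607 genes, against 13450, 14520 and 14533. The remaining splits put like numbers into 1 group, so differences between replicate numbers enter them. Every split but the real one also mixes the nutrient groups compared. Their difference then enters the residual spread, which lowers the calls by construction, so the low counts do not bear on chance. Against depleted cells, turning the sign of arrays gives 8 patterns, too few for a share under 0.05. The real pattern was the only 1 to call as many, with 13111, 16329 and 15984 genes against at most 3, 6 and 11. Turning some arrays also moves the ratio they share into the residual spread, which lowers the calls by construction, so these low counts do not bear on chance either. For the interaction 1 of 100 drawn splits of the 12 arrays, the real one with 12460 genes, gave as many, but another split called 8427. By construction every split keeps the ratio shared by all 12 arrays in this contrast, with its sign turned, so these splits do not stand for the absence of an interaction, and whether chance is excluded stays open there.

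In a limma test against a margin of log2 1, the glutamine effect differed between cells with and without glucose in 50 named genes. Other named genes had values beyond log2 1 that did not pass this test and are not listed. The interaction was negative in 43 of them, at -4.62 for HMOX1, -4.43 for HERPUD1, -3.93 for TRIB3, -3.27 for EGR1, -3.26 for CTH, -3.25 for HSPA6, -3.15 for DDIT3 and for LCN2, -3.12 for DNAJB9 and -3.10 for FOS. It was -2.93 for ZNF165, -2.92 for BHLHA15, -2.72 for GDF15, -2.65 for CHAC1, -2.63 for ZFAND2A and for ATF3, -2.55 for ATF4, -2.52 for CXCL2, -2.39 for HSPA5, -2.38 for ERO1B, -2.36 for XBP1, -2.28 for SLC7A11, -2.27 for HSPA1A and -2.23 for IFI6. Next came CCN2 at -2.14, CXCL1 at -2.13, MANF and AREG at -2.06, ASNS at -2.02, WIPI1 at -2.00, JDP2 at -1.97, CXCL3 at -1.81, CXCL8 at -1.77, ARRDC4 at -1.73, ERRFI1 at -1.70, HSP90B1 at -1.64 and GARS1 at -1.63. The last negative values past the test were HBP1 at -1.44, STARD4 at -1.42, GABARAPL1 at -1.40, GCLM at -1.38, MXD1 at -1.31 and IL1A at -1.23. For ATF4 a further probe read -0.18 with glucose alone, against 0.33 on the chosen probe, and that ratio enters the interaction. For HSPA5 a further probe read 0.29 in both against glucose, where the chosen probe read -0.64. The interaction was positive for OGT at 1.88, although a further OGT probe read 0 with glutamine alone and -0.04 in both against glucose. It was also positive for BMP7 at 1.78, ANP32D at 1.71, HAS2 at 1.55, DST at 1.44, IL33 at 1.30 and RFLNB at 1.18. Further DST probes moved less with glucose alone, as given above. A further RFLNB probe read 0.22 with both nutrients against depleted cells, where the chosen probe read -0.15. These ratios enter the interaction too.

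In 22 of 513 groups of 4 arrays (171 named genes in 3 groups) 1 array stood apart, its gap to the next, as a share of the group's range, being over Dixon's 95% limit for 4 arrays. Chance alone sets about 5% of groups apart in this way. With glucose these were CENPA at 0.974, DUSP6 at 0.931, RELB at 0.887, DTL at 0.858, SESN1 at 0.853 and HAS2 at 0.842. With glutamine they were PIR at 0.924, PHGDH at 0.915, ALDH18A1 at 0.882, COX6C at 0.872, MXD3 at 0.847, DSCC1 at 0.842, BHLHA15 at 0.835 and DERL3 at 0.831. With both they were LDHA at 0.932, AARS1 at 0.908, HK2 at 0.895, STARD4 at 0.883, LFNG at 0.869, ACAT2 at 0.861, BMP7 at 0.853 and HSPA5 at 0.849.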

How the results depend on the processing

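Of the tests described here, the Cy5 channel alone was chosen only after the result was seen. Aquantile normalization changed no probe's ratio, though 5 genes took another probe, and the series table repeats the software's ratio, so both are left out of the following totals. Over 5475 alternative values of named genes, 5427 kept direction and side of the threshold, 35 lost the call, 2 gained it and 11 reversed. Most of these genes were named for the size or low p of their change in these same data, which favours kept calls. The totals for named genes therefore do not speak for the other genes called. Over 2919 alternative values of lists, 2714 kept camera's direction and the side of the threshold, 113 lost the call, 87 gained it and 5 reversed in direction. An estimated correlation accounts for 52 of the losses. Of the gains 65 came from fry, which tests against no change and not against other genes. In 11 of the lost calls, all under median centring, the median changed sign as well. The split of the calls into higher and lower moved further under median centring, as given above. The total counts of genes called per comparison stayed within 1.5 times of the reported ones under every alternative except the added limit of log2 1. That limit, which asks for more by its construction, left 65 genes with glucose, 445 with glutamine and 796 with both against depleted cells, 414 for both against glucose, 569 for both against glutamine, 466 for glucose against glutamine and 579 for the interaction. With each array left out in turn the counts were 11850 to 12199, 15466 to 15599, 15117 to 15336, 11819 to 12265, 12971 to 13355, 12979 to 13690 and 11808 to 12330, in the same order. With the replicate block they were 14131, 17030, 16603, 13594, 14654, 14621 and 13531, of which 13034, 16270, 15920, 12429, 13643, 13680 and 12375 were shared with the reported calls. A block for slide or scan session was not run, since each session held 1 group.

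Under median centring ASNS with glutamine reversed to 0.563, DDX21 with glucose to 0.037, FTL with glutamine to 0.508, SC5D with both to 0.249, SLBP with glutamine to 0.26, and SLC2A1 to 0.607 with glucose and to 0.143 in both against glutamine. It also reversed camera's direction for aminoacyl-tRNA synthetases with glucose (median 0.393), oxidative phosphorylation in both against glutamine (0.286) and ribosome biogenesis with both (0.471), besides the 11 medians of lost calls. By its construction median centring leaves the intensity trend that loess removes, and bright genes then read high. With the mean of a gene's probes HK2 with glutamine reversed to -0.18 and NPM1 with glucose to -0.243, because further probes of both genes read lower. NPM1 with glucose was also -0.032 with the software's ratio and in the series table, and MXD3 in both against glucose was -0.027 in the Cy5 channel alone, and the cause was not tested. The fry test put the hexosamine list with glutamine (median 0.087) and the stromal list with glucose (median 0.121) in the direction opposite to camera, both far from camera's threshold. Genes dim in both channels limit what can be seen, as 64.4% to 72% of probes in green and 67.3% to 80.1% in red were well above background, and the strictest filter left 144 of the 150 list tests.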

Other observations

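The heat shock genes described here, and their test, were chosen only after the result was seen, because HSPA6, ZFAND2A and HSPA1A stood high with glutamine alone. These genes code for chaperones and their helpers, many of which are known to be switched on by damaged protein. With glutamine alone 11 of 21 measured genes rose, 4 of them by log2 1 or more, and 4 fell. As a list they did not pass (median 0.16, camera adjusted p = 0.071, adjusted p = 0.28 with an estimated correlation). HSPA6 was at 3.40, ZFAND2A at 2.31, HSPA1A at 2.04, DNAJB1 at 1.46 and HSPE1 at 0.91, while HSPA8 was at -0.33, HSPA4L at -0.75 and HSPB1 at -0.20. HSP90AA1 at 0.05 was not called (limma adjusted p = 0.38). With both nutrients 13 rose and 3 fell (median 0.21, camera adjusted p = 0.071, adjusted p = 0.28 with an estimated correlation). HSPE1 was at 1.08, HSPA8 at 1.00 and HSP90AA1 at 0.80, whereas ZFAND2A was at -0.20 and DNAJB1 at -0.07 was not called (limma adjusted p = 0.25). With glucose alone 8 rose and 4 fell (median 0.06, camera adjusted p = 0.23, adjusted p = 0.41 with an estimated correlation), with HSPA1A at 1.1 and HSPA6 at -0.89.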
